A study of Homo sapiens with 24 samples.

How the data were processed

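RNA of MCF7 cells was measured in 4 fractions (total RNA, polysomal RNA, riboLace and mP beads) under 3 conditions (control, starved for 12 h in 0.5% serum, starved for 12 h and then given EGF for 4 h), with 2 files per group and 24 in all. Per the labels, cells were grown to 80% confluence and given cycloheximide at 10 µg/mL for 5 min before lysis, nuclei were removed, and poly(A)-enriched RNA was made into TruSeq v2 libraries of 274 bp mean fragment length. Single reads were taken on a HiSeq 2000 with 12 samples per lane. The labels do not say whether the counting was strand-specific.

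The deposited values are FPKM per gene, made by the authors; the labels name FastQC, TopHat2 2.0.14, Cufflinks 2.2.1 and genome GRCh38.p2, and state no annotation. The values keep the scale of each column. Gene symbols, identifiers and 1-based locus positions are those of the table, and RNA types came from a gene table matched to 56357 of 60469 gene identifiers. Left out were 7371 genes for small RNAs, chosen by symbol as shorter than the fragments (406 of them with a mean of at least 1 FPKM), and 24 genes that shared a symbol. Tested were the 14359 genes with a mean of at least 1 FPKM, as log2 of FPKM + 1. Of 7678 genes with a median of at least 10 FPKM, 30 are listed at 0 in some file, and such zeros were kept.

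Read counts were not used here, and depth was estimated from the FPKM step that a single read makes. Of 24363 genes examined, 5940 had values that were whole multiples of a step within 0.01, and 23 single-exon genes with a length offset of 184.07 bp set the scale. The estimates were 11.2 to 17.1 M reads per file. Among genes of at least 100 FPKM the 2 files of a group had a robust SD of the log2 difference of 0.0488 to 0.0706, and 84 to 151 genes lay 2-fold apart.

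The design written before any value was seen was a limma fit of 24 libraries in 12 group means, with the 2 files of a group as replicates, as the labels describe them. Before any fit, a check of the values found the files of a group too alike: a chi-square test of estimated reads over 9 mitochondrial genes gave p above 0.05 in 10 of 12 groups. The exceptions were total RNA with EGF (chi-square 36.4, p = 1.51e-05) and riboLace of starved cells (19, p = 0.015). The main fit was therefore changed after this check, and so after the data were seen, but before the counts of either fit: files of a group were averaged into 12 merged libraries, and limma 3.58.1 fitted fraction plus condition with a trended empirical Bayes variance and 1 weight per fraction (total RNA 0.991, polysomal RNA 0.825, riboLace 1.234, mP beads 0.991). It had 6 residual degrees of freedom and 3.51 prior degrees of freedom, and Benjamini-Hochberg adjusted p under 0.05 was the threshold. The design's fit was run beside it, and its counts per fraction were, for starved against control, 5185 in total RNA, 5625 in polysomal RNA, 6260 in riboLace and 6626 in mP beads RNA. For EGF against starved they were 4116, 4042, 5497 and 4398, and for EGF against control 5682 in total RNA and 5872 in riboLace. For the difference of the starvation change from total RNA they were 2367 (riboLace) and 1360 (polysomal RNA), and for EGF 1693 and 421. They take the 2 files as independent and are not used in the report.

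Conditions were compared over the 4 fractions and fractions over the 3 conditions. Changes within a fraction, and their differences between fractions, have n = 1 and are given by size: genes count as 2-fold apart with at least 5 FPKM in the higher group and no overlap between the files. The 19 gene lists were written before any value was seen: immediate early genes, ERK feedback and the delayed EGF response, estrogen receptor targets, cytosolic ribosomal proteins, other TOP mRNAs, ribosome biogenesis, cholesterol biosynthesis, FOXO targets and quiescence, G1/S and DNA replication, mitosis, ATF4 targets, ER chaperones, SRF and cytoskeletal genes, secreted and membrane proteins, nuclear-encoded oxidative phosphorylation, mitochondrially encoded mRNAs, nuclear-retained RNAs, snoRNA hosts and markers of other cell types. Each was tested with camera in limma at a preset inter-gene correlation of 0.01 and with a correlation estimated from the residuals, adjusted over the 19 lists. Counts "adjusted over the list alone" repeat the adjustment over the members. List medians within a fraction were ranked against 10000 random lists matched on expression. These were drawn from all tested genes of like expression, and the list's own members were not removed.

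Genes were named by a rule written beforehand: the 6 largest rises and 6 largest falls among genes past the test, with at least 5 FPKM in the higher group and no overlap between the compared libraries (for fractions, the same direction in every pair), and up to 4 members of each list with the smallest p. MYC, EGR1, DUSP6, CCND1 and HMGCS1 were added for EGF. Genes with no symbol were not named. For comparisons that share libraries, 20 simulations without an effect gave the correlation to be met by chance.

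Alternatives were a pseudocount of 0.1, no filter, a mean of at least 5 FPKM, median-of-ratios scaling, small RNA genes kept, each file left out, equal weights, only the compared libraries, a replicate block and an estimated list correlation. For fractions the block came in an additive fit of fraction plus condition with replicate number. Chosen after seeing the data were the merged libraries, the comparisons of conditions over the 4 fractions together with all their alternatives, the counts of genes 2-fold apart, leaving out each fraction or condition, and leaving out the mP beads control library. The 24 files as replicates were the planned fit for the comparisons of fractions. The main fit was tested on simulated data: of simulated changes of log2 0.5, 1 and 2 for starved against control, 56.1, 91 and 94% were recovered, with 4.17% false calls. For riboLace against total RNA 48.5, 86.6 and 97% were recovered, with 6.63% false calls. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3 with its data.table package (1.17.8) were used.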

Results

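MCF7 cells, an established line from an estrogen receptor-positive breast carcinoma, were sampled while growing (control), after 12 h in medium with 0.5% serum (starved), and after starvation followed by 4 h with epidermal growth factor (EGF). Polyadenylated RNA was sequenced from 4 fractions of the cytoplasmic lysate: total RNA, polysomal RNA, RNA pulled down with riboLace, a capture of ribosomes in translation, and RNA pulled down with mP beads, a name the labels do not expand. The mP beads may be another capture or a control for RNA that binds the beads, which changes what their likeness to riboLace means. Each of the 12 groups held 2 files, 24 in all, with 1 FPKM value per gene and file. The depth estimated from the values was 11.2 to 17.1 M reads per file and was lowest in the mP beads control files. The labels call the 2 files of a group biological replicates, yet their reads over 9 mitochondrial genes differed by a chi-square of only 3.15 to 36.4 on 8 degrees of freedom, against 585 to 6976 between files of different conditions. Their estimated depths differed by 0.164 to 0.888%, which decides less, since a total RNA and a riboLace file came within 0.431%. Over genes with 5 to 29 reads in a pair of files, the median chi-square was 1.082 to 1.151 times that expected within a group. Between files of different conditions it was 1.284 to 2.692 times. For riboLace and mP beads of starved cells it was 1.069 times, so this measure did not separate these from files of a group. The 2 files of each group were therefore averaged and counted as 1 merged library, which leaves n = 1 for every fraction and condition. Comparisons of conditions rest on the 4 fractions and comparisons of fractions on the 3 conditions, and since fractions may come from the same cultures, the p-values measure how well they agreed and not the spread between cultures. A change within a single fraction has no replicate check and is given by its size. Of the 15 listed markers of other cell types, 1 reached a mean of 1 FPKM, the collagen gene COL1A1.

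The starved cells were compared with growing cells to show which mRNAs respond to the loss of serum. The largest rise was in GPNMB, which encodes a glycoprotein of lysosomes and melanosomes (ENSG00000136235.14, chromosome 7, 23235967 to 23275108 on GRCh38.p2). It went from 2.59 to 39.5 FPKM in total RNA and rose by a log2 difference of 3.80 over the 4 fractions (SE 0.12, limma adjusted p = 5.82e-07, n = 4 merged libraries per side). FAM84A (1.91), the histone genes HIST1H4H (1.84) and HIST2H2BE (1.82), AVPI1 (1.80) and SGPP1, a phosphatase of sphingosine 1-phosphate (1.74), rose next. The largest falls were in PABPC1L, a relative of the poly(A)-binding protein (log2 difference −2.40, SE 0.18, limma adjusted p = 4.11e-05), in the growth-induced transcription factor EGR1 (−1.93), in CSAD, an enzyme of taurine synthesis (−1.74), and in SH3BP5-AS1 (−1.67), CCDC84 (−1.58) and MRI1, an enzyme of methionine salvage (−1.56). SH3BP5-AS1 lies antisense to another gene, and no strand-specific counting is stated, so its reads are uncertain. In all, 5202 of 14359 genes passed, 2526 higher and 2676 lower (2179 and 1966 among genes with a mean of at least 5 FPKM). With the 24 files counted as replicates the number was 8831.

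Genes of growth arrest rose together. Of 18 measured FOXO targets and quiescence genes, 16 rose and none fell (16 adjusted over the list alone), with a median log2 difference of 0.59 (camera adjusted p = 1.13e-10; adjusted p = 0.0453 with an estimated correlation). Among them, TP53INP1, a regulator of autophagy, rose by 1.64, the cyclin G2 gene CCNG2 by 1.52, the co-regulator CITED2 by 1.34 and YPEL3 by 1.24. In the same libraries 21 of 25 genes of G1/S and DNA replication fell and none rose (22 lower adjusted over the list alone), with a median of −0.41 (camera adjusted p = 3.28e-08; adjusted p = 0.0514 with an estimated correlation). The replication factors CDC45 and MCM10 fell by 0.87 and 0.84, and UHRF1 and GINS1 fell by 0.51 and 0.48. Genes of ribosome biogenesis fell as well, 17 of 24 (19 adjusted over the list alone), with a median of −0.29 (camera adjusted p = 3.63e-06; adjusted p = 0.496 with an estimated correlation). MYBBP1A and NOP2, both of the nucleolus, fell by 0.72 and 0.71, and NOP58 and NOLC1 fell by 0.47 and 0.40.

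The immediate early genes divided. Of 18 measured, 8 rose and 5 fell (11 and 5 adjusted over the list alone; camera adjusted p = 0.196): the MAP kinase phosphatase DUSP1 rose by 1.66, while EGR1, EGR3 (−1.30) and the oncogene MYC (−1.10) fell. Estrogen receptor targets held 3 higher and 8 lower of 20 (4 and 8 adjusted over the list alone; camera adjusted p = 0.0644), with the carbonic anhydrase CA12 at −1.16, GREB1 at −0.59, the chemokine CXCL12 at −0.53 and the receptor kinase RET at −0.48. Of 28 genes for secreted and membrane proteins, 15 rose and 3 fell (15 and 3 adjusted over the list alone; median 0.26; camera adjusted p = 0.000338, and adjusted p = 0.615 with an estimated correlation), led by the sodium pump subunit ATP1B1 (1.55), the syndecan SDC4 (0.85) and ERBB2 (0.63). ATF4 targets of the amino acid response went both ways, 8 higher and 7 lower of 19 (8 and 8 adjusted over the list alone; camera adjusted p = 0.6): PPP1R15A rose by 1.16, SESN2 by 0.71 and DDIT4 by 0.67, while asparagine synthetase, ASNS, fell by 0.64. Mitosis genes held 7 higher and 1 lower of 20 (8 and 1 adjusted over the list alone; median 0.19; camera adjusted p = 0.0242, and adjusted p = 0.615 with an estimated correlation), with AURKA at 0.41, PTTG1 at 0.40, KIF20A at 0.39 and the proliferation marker MKI67 at −0.32. The nuclear RNAs NEAT1 and MALAT1 fell by 1.22 and 1.23, and both were most abundant in the mP beads control library, which had the lowest depth, where they read 333 and 75.3 FPKM, against 104 and 17.7 FPKM in starved cells. COL1A1 fell by 0.80. Cholesterol biosynthesis, the ERK feedback list, ER chaperones, SRF targets, mitochondrially encoded mRNAs, nuclear-retained RNAs and the host RNAs of snoRNAs did not pass camera's test in this comparison.

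Ribosomal protein mRNAs had starvation medians of opposite sign in total and polysomal RNA, a difference that was not tested. All 79 had a log2 difference above 0 over the 4 fractions together, with a median of 0.23, 7 of them past the test over all genes and none adjusted over the list alone (camera adjusted p = 8.53e-06; adjusted p = 0.755 with an estimated correlation). The median was 0.38 in total RNA and −0.24 in polysomal RNA, where 74 of 79 lay below 0, with 0.37 in riboLace and 0.29 in mP beads RNA. Against 10000 random lists matched on expression, which had medians of 0.21 in total and −0.11 in polysomal RNA, the list lay at the 100th and the 0.04th percentile. In riboLace and mP beads RNA the matched lists had 0.31 and 0.32, and the list, at percentiles 91.87 and 20.23, did not stand apart from them. Ribosomal protein genes could be drawn into their own matched lists, so these do not show what other abundant genes did. The 19 other mRNAs with a 5′ terminal oligopyrimidine (TOP) motif, which encode translation factors such as EEF2 and EIF4B, had medians of 0.51 in total RNA, 0.05 in polysomal RNA, 0.30 in riboLace and 0.33 in mP beads RNA. Matched lists had 0.12, −0.10, 0.27 and 0.31, so the pull-down values, at percentiles 63.85 and 60.3, did not stand apart from matched lists. Over the fractions together 9 of the 19 rose (12 adjusted over the list alone; camera adjusted p = 0.000305, and adjusted p = 0.615 with an estimated correlation), with EEF2 at 0.77 and EIF4B at 0.65. Nuclear-encoded oxidative phosphorylation mRNAs had a median of 0.48 in riboLace and 0.47 in mP beads RNA, beside −0.05 in total and −0.11 in polysomal RNA, where matched lists had 0.25, 0.29, 0.08 and −0.10. Of these 31, 10 rose over the fractions together (9 adjusted over the list alone; camera adjusted p = 0.00446, and adjusted p = 0.755 with an estimated correlation), COX6C by 0.57 and NDUFA1 by 0.60. The 13 mitochondrially encoded mRNAs had medians of 0.21 and 0.38 in total and polysomal RNA and of −0.32 and −0.63 in riboLace and mP beads RNA.

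**Figure D1:**
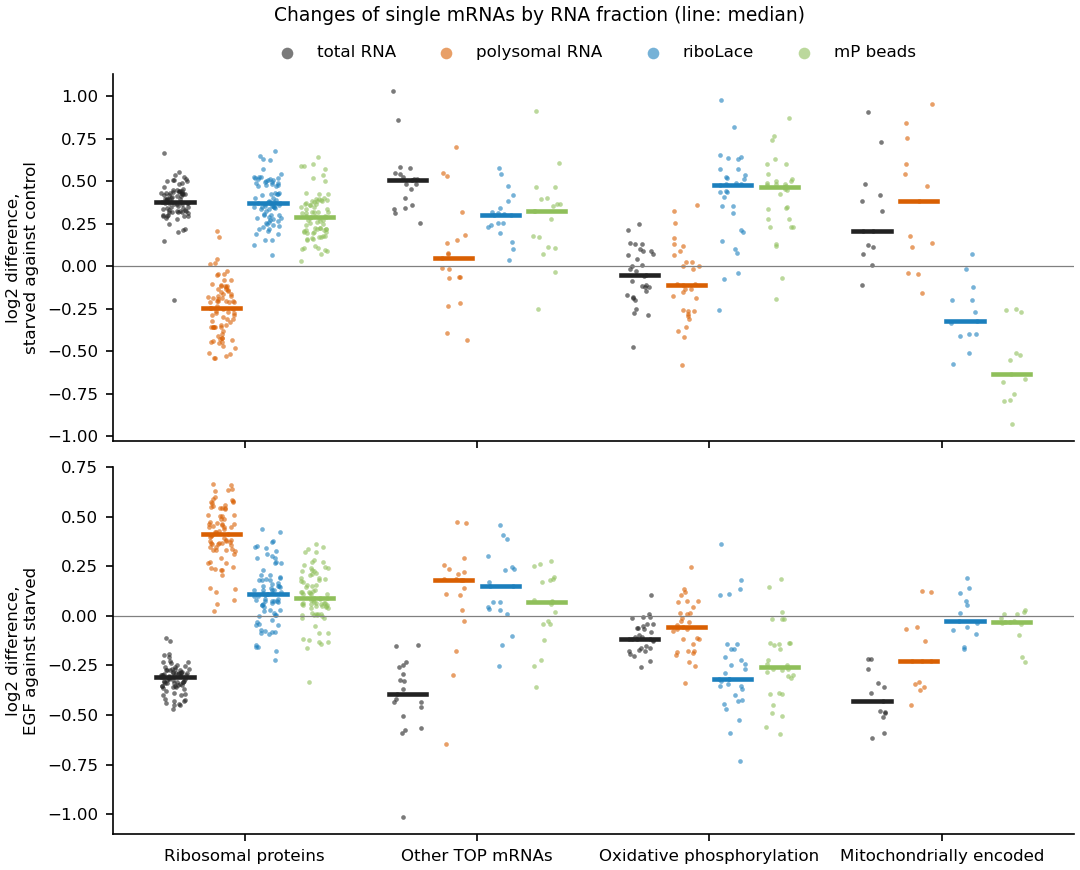
Log2 difference of single mRNAs (vertical axis, on log2 of FPKM + 1) in 4 gene lists, for starved against control cells (top) and EGF against starved cells (bottom), with 1 point per gene and a line at each median. Colours mark the 4 RNA fractions, each n = 1 merged library per condition; ribosomal protein mRNAs have medians of 0.38 in total and −0.24 in polysomal RNA on starvation, and of −0.31 and 0.41 on EGF.

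Within single fractions, 212 genes were at least 2-fold apart between starved and control cells in total RNA (132 higher, 80 lower), 236 in polysomal RNA (139 higher, 97 lower), 300 in riboLace (126 higher, 174 lower) and 635 in mP beads RNA (148 higher, 487 lower). These counts need at least 5 FPKM in the higher group and files that do not overlap, and they have no replicate check. Without the rule on overlap, the first files of control and starved cells had 331 to 764 genes 2-fold apart, against 84 to 151 between the 2 files of a group. The mP beads count was 410 among genes with a mean of at least 5 FPKM.

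EGF was added to starved cells to show which mRNAs respond to the growth factor. The potassium channel gene KCNF1 rose most among reliably assigned genes, from 2.71 to 12.2 FPKM in total RNA and by a log2 difference of 1.96 over the fractions (SE 0.08, limma adjusted p = 1.09e-05, n = 4 merged libraries per side; chromosome 2, 10911937 to 10914225 on GRCh38.p2). A larger value, 2.26, belonged to TGIF2-C20orf24, a readthrough of neighbouring genes whose assignment is uncertain. The cytokine gene CLCF1 (1.32), the chemokine receptor CXCR4 (1.31), PABPC1L (1.29) and the sphingosine 1-phosphate transporter SPNS2 (1.20) followed. These ranks are of genes with at least 5 FPKM in the higher group and no overlap between the compared libraries. The largest falls were in PSCA, a surface antigen (−1.33, SE 0.09, limma adjusted p = 7.76e-05), the MAX partner MXD3 (−1.19), H1FX-AS1 (−1.19), RAET1E-AS1 (−1.18), OSER1-AS1 (−1.10) and TMEM160 (−1.10), of which the 3 antisense genes are uncertain. A total of 3407 genes passed, 1828 higher and 1579 lower. With the 24 files counted as replicates the number was 7949.

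Targets of the ERK pathway rose with EGF. Of 12 measured genes of ERK feedback and the delayed EGF response, 9 rose and none fell (9 adjusted over the list alone), with a median log2 difference of 0.69 (camera adjusted p = 2.13e-08; adjusted p = 0.0295 with an estimated correlation). PHLDA1 rose by 1.02, the EGF receptor inhibitor ERRFI1 by 1.00, the urokinase receptor PLAUR by 0.78 and the EGF receptor ligand AREG by 0.60. PHLDA1 was low, at 0.98 FPKM in starved and 3.58 FPKM in EGF-treated total RNA. At such levels the 1 FPKM added before the log2 makes a change smaller. DUSP6, a feedback phosphatase of ERK, had a mean of 0.876 FPKM, below the filter, and read 0.58 FPKM in starved and 0.96 FPKM in EGF-treated total RNA. SRF and cytoskeletal genes rose in 9 of 17 cases (10 adjusted over the list alone; median 0.36; camera adjusted p = 8.51e-05, and adjusted p = 0.137 with an estimated correlation), with FHL2 at 1.48, the focal adhesion protein zyxin, ZYX, at 1.14 and CNN2 at 0.83. FHL2 was also low, at 0.69 FPKM in starved and 4.17 FPKM in EGF-treated total RNA. Among immediate early genes 7 of 18 rose and 1 fell (8 and 1 adjusted over the list alone; camera adjusted p = 0.0147, and adjusted p = 0.137 with an estimated correlation). EGR1 rose by 0.83, with 0.95 in total, 0.80 in polysomal, 0.71 in riboLace and 0.88 in mP beads RNA, and FOSL1 rose by 0.91, whereas MYC fell by 0.34, with −0.38, −0.42, −0.32 and −0.24 in the same order. Cyclin D1, CCND1, rose by 0.40, with 0.42, 0.63, 0.37 and 0.24.

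Of 24 ribosome biogenesis genes, 20 rose and none fell (22 adjusted over the list alone), with a median of 0.47 (camera adjusted p = 8.28e-13; adjusted p = 0.12 with an estimated correlation). NOP16 rose by 0.77, the helicase DDX21 by 0.75, LYAR by 0.65 and NIP7 by 0.54. Of 23 cholesterol biosynthesis genes, 14 rose and 1 fell (16 and 1 adjusted over the list alone; median 0.28; camera adjusted p = 1.88e-07, and adjusted p = 0.137 with an estimated correlation). HMGCS1, the synthase of the mevalonate precursor HMG-CoA, rose by 0.74, with 0.80 in total, 0.67 in polysomal, 0.83 in riboLace and 0.61 in mP beads RNA, and MSMO1 and CYP51A1 rose by 0.53 and 0.51. In G1/S and DNA replication 7 of 25 rose and none fell (7 adjusted over the list alone; camera adjusted p = 0.000117, and adjusted p = 0.12 with an estimated correlation), with cyclin E1, CCNE1, at 0.85, CDC25A at 0.70 and MCM10 at 0.64. ATF4 targets rose in 9 of 19 cases (10 adjusted over the list alone; camera adjusted p = 0.00152, and adjusted p = 0.203 with an estimated correlation), among them CHAC1 (0.65) and the serine synthesis gene PSAT1 (0.54).

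FOXO targets fell after EGF, 13 of 18 (16 lower and 1 higher adjusted over the list alone), with a median of −0.52 (camera adjusted p = 6.52e-10; adjusted p = 0.0295 with an estimated correlation). YPEL3 fell by 1.05, the PI3-kinase inhibitor PIK3IP1 by 1.04, the thioredoxin inhibitor TXNIP by 1.02 and HBP1 by 0.81. Mitosis genes fell in 6 of 20 cases (6 adjusted over the list alone; camera adjusted p = 0.000378, and adjusted p = 0.288 with an estimated correlation), CENPF by 0.59. Of the oxidative phosphorylation mRNAs, 27 of 31 lay at or below 0 and COX5B alone passed, at −0.47 (none adjusted over the list alone; camera adjusted p = 0.0015, and adjusted p = 0.736 with an estimated correlation). Host RNAs of snoRNAs held 5 higher and 1 lower of 16 (5 and 1 adjusted over the list alone; camera adjusted p = 0.0474, and adjusted p = 0.736 with an estimated correlation), with SNHG15 at 0.80, SNHG3 at 0.79, SNHG12 at 0.79 and SNHG17 at 0.66. Ribosomal proteins, other TOP mRNAs, estrogen receptor targets, ER chaperones, secreted and membrane proteins, mitochondrially encoded mRNAs and nuclear-retained RNAs did not pass camera's test over the fractions together. By fraction, the ribosomal protein mRNAs had a median of −0.31 in total RNA, with all 79 below 0, and of 0.41 in polysomal RNA, with all 79 above 0, where matched lists had −0.19 and 0.07. Their medians in riboLace and mP beads RNA were 0.11 and 0.09. The other TOP mRNAs read −0.39, 0.18, 0.15 and 0.07 in total, polysomal, riboLace and mP beads RNA. Within single fractions, 99 genes were 2-fold apart in total RNA (50 higher), 111 in polysomal RNA (61 higher), 123 in riboLace (69 higher) and 137 in mP beads RNA (77 higher), with no replicate check. Without the rule on overlap, the first files of starved and EGF-treated cells had 204 to 248, against 84 to 151 between the 2 files of a group.

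**Figure D2:**
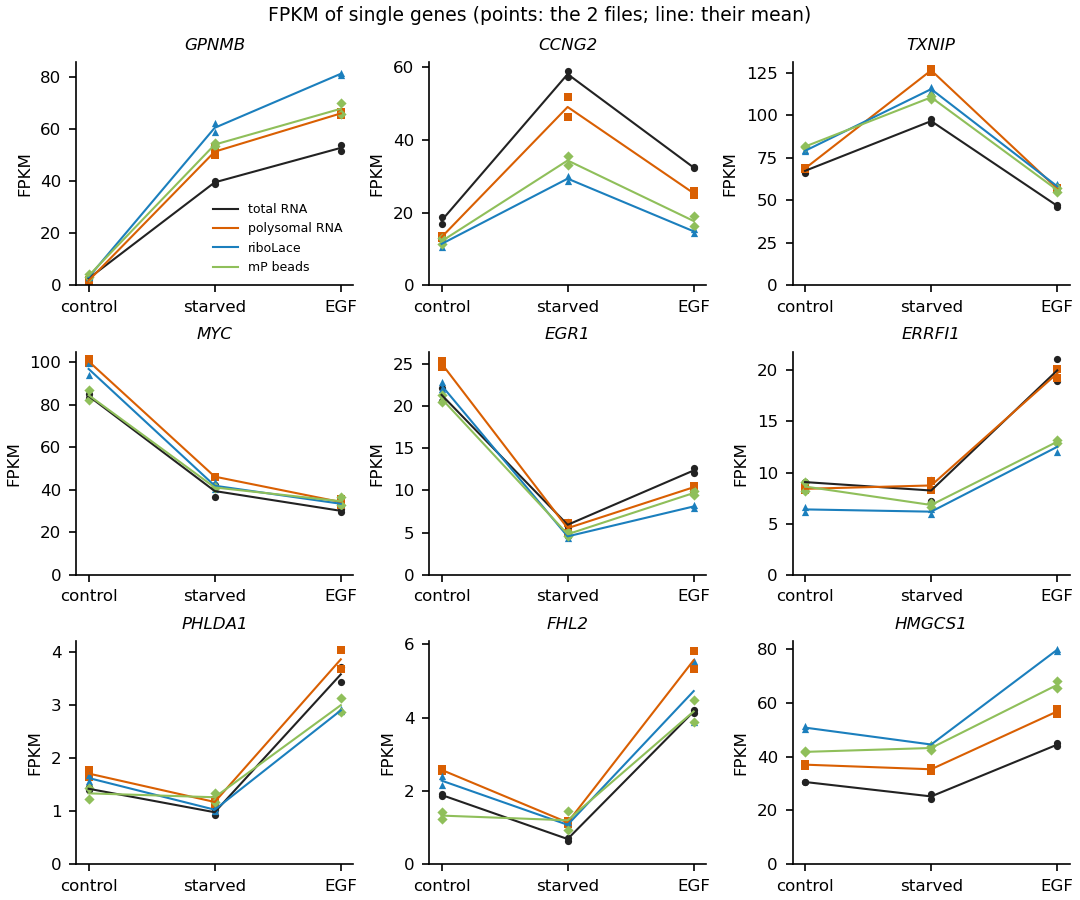
FPKM (vertical axes, each from 0) of 9 genes in control, starved and EGF-treated cells, with points for the 2 files of each group and lines through their means. Colours mark the 4 RNA fractions; GPNMB in total RNA goes from 2.59 to 39.5 and 52.7 FPKM, and MYC from 84.1 to 39.4 and 30.1 FPKM.

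EGF-treated cells were also set against growing cells. The log2 differences leave out the starved libraries, which still enter the p-values through the shared estimate of spread. GPNMB stayed highest, at a log2 difference of 4.18 (SE 0.12, limma adjusted p = 1.72e-07, n = 4 merged libraries per side), followed by CXCR4 (2.27), TNFRSF11B, the decoy receptor osteoprotegerin (2.17), ATP1B1 (2.01), AVPI1 (1.99) and LYPD1 (1.95). HSH2D (−1.71), C15orf59 (−1.60), the antisense gene SH3BP5-AS1 (−1.52), MYC (−1.44), LRRC26 (−1.41) and TTC38 (−1.39) were lowest. In all 5057 genes passed, 2571 higher and 2486 lower, and 4009 when only the compared libraries were fitted. With the 24 files counted as replicates the number was 8982. ERK feedback genes were higher in 11 of 12 cases (12 adjusted over the list alone; median 0.82; camera adjusted p = 9.11e-08, and adjusted p = 0.0469 with an estimated correlation), DUSP5 by 1.15. Immediate early genes held 13 higher and 5 lower of 18 (13 and 5 adjusted over the list alone; camera adjusted p = 0.00543, and adjusted p = 0.271 with an estimated correlation), with DUSP1 at 1.52, CYR61 at 1.16 and JUN at 1.02. Of the G1/S genes 3 were higher and 11 lower (3 and 12 adjusted over the list alone; camera adjusted p = 0.00627, and adjusted p = 0.381 with an estimated correlation), CCNE1 by 0.76 and CDC45 by −0.67. Estrogen receptor targets held 1 higher and 8 lower of 20 (2 and 8 adjusted over the list alone; camera adjusted p = 0.0269, and adjusted p = 0.381 with an estimated correlation), with CA12 at −1.21 and IGFBP4 at −0.87. FOXO targets held 9 higher and 4 lower genes of 18 (9 and 5 adjusted over the list alone; camera adjusted p = 0.144), with CITED2 at 1.54. Within single fractions 280 genes lay 2-fold apart in total RNA (188 higher) and 250 in riboLace (131 higher). With 1 file per group they were 411 to 422 in total RNA. In riboLace more were then lower than higher (179 against 163, and 176 against 166).

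More lists passed camera in EGF-treated against growing cells at the preset correlation only. Ribosomal protein mRNAs were higher in 17 of 79 cases and lower in none (none adjusted over the list alone; median 0.30; camera adjusted p = 9.11e-08, and adjusted p = 0.572 with an estimated correlation). Cholesterol biosynthesis genes held 12 higher and 2 lower of 23 (12 and 2 adjusted over the list alone; median 0.38; camera adjusted p = 0.000233, and adjusted p = 0.381 with an estimated correlation). For secreted and membrane proteins it was 15 and 3 of 28 (16 and 3 adjusted over the list alone; median 0.27; camera adjusted p = 0.000995, and adjusted p = 0.478 with an estimated correlation). For other TOP mRNAs it was 8 and 0 of 19 (10 and 0 adjusted over the list alone; median 0.27; camera adjusted p = 0.00102, and adjusted p = 0.516 with an estimated correlation). Ribosome biogenesis held 7 higher and none lower of 24 (7 adjusted over the list alone; median 0.13; camera adjusted p = 0.00369, and adjusted p = 0.478 with an estimated correlation). SRF and cytoskeletal genes held 9 higher and 1 lower of 17 (10 and 1 adjusted over the list alone; median 0.31; camera adjusted p = 0.00375, and adjusted p = 0.381 with an estimated correlation). ATF4 targets held 11 higher and 4 lower of 19 (11 and 5 adjusted over the list alone; median 0.31; camera adjusted p = 0.00627, and adjusted p = 0.381 with an estimated correlation).

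Comparisons of starved with control and of EGF with starved cells use the same starved libraries. Across genes their log2 differences correlated at −0.41, with a covariance of −0.0505, where libraries simulated without an effect gave −0.493 and −0.0185. Of the genes that passed both tests, 672 were higher on starvation and lower on EGF and 833 the reverse, against 277.8 and 340.7 for independent lists. Both higher were 170 genes (321.6 for independent lists) and both lower 85 (294.3). Part of these overlaps may come from the shared starved libraries, which are too few to divide. When the starvation change in a fraction was set against the EGF change in another, with no library shared, the correlation across genes was −0.197 to −0.04 (Spearman −0.368 to −0.074). Fractions may come from the same cultures, and a deviation of the starved cultures would then enter both changes with opposite sign. These correlations therefore cannot tell a reversal by EGF from such a deviation.

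RiboLace RNA was compared with total RNA to show which transcripts the ribosome capture held. The splicing factor PRPF8 was highest relative to total RNA (log2 difference 2.68, SE 0.22, limma adjusted p = 2.01e-05, n = 3 conditions), at 346 against 71.8 FPKM in control cells, followed by the topoisomerase TOP2A (2.67), the DNA-dependent protein kinase PRKDC (2.51), the myosin MYH9 (2.35), the fatty acid synthase FASN (2.27) and CHD4 (2.25), all of which encode large proteins. The mitochondrial ribosomal RNAs MT-RNR1 and MT-RNR2 were lowest, at −3.29 and −3.25, with MT-CO2 at −2.92, the non-coding LINC00674 at −2.71 and MT-CO3 at −2.56. TMSB4XP6, at −3.19, is a pseudogene that shares reads with its parent and is uncertain. In all 7356 genes passed, 3217 higher and 4139 lower (3682 and 3624 with median-of-ratios scaling), and 4831 without the EGF libraries. All 13 mitochondrially encoded mRNAs were lower (13 adjusted over the list alone; median −1.80; camera adjusted p = 2.04e-07, and adjusted p = 0.519 with an estimated correlation), as were 74 of 79 ribosomal protein mRNAs (76 adjusted over the list alone; median −1.03; camera adjusted p = 2.09e-18, and adjusted p = 0.521 with an estimated correlation), RPLP0 by −2.10. Host RNAs of snoRNAs were lower in 9 of 16 cases (9 adjusted over the list alone; median −0.64; camera adjusted p = 0.00267, and adjusted p = 0.521 with an estimated correlation), SNHG16 by −2.01. Ribosome biogenesis genes were higher in 20 of 24 cases (22 adjusted over the list alone; median 0.63; camera adjusted p = 2.2e-09, and adjusted p = 0.318 with an estimated correlation), MYBBP1A by 1.64 and nucleolin, NCL, by 1.05. Mitosis genes were higher in 16 of 20 cases and lower in 1 (16 and 1 adjusted over the list alone; median 0.51; camera adjusted p = 1.83e-07, and adjusted p = 0.318 with an estimated correlation), CENPF by 1.82 and MKI67 by 1.66. ER chaperones were higher in 11 of 18 cases and lower in 3 (11 and 3 adjusted over the list alone; median 0.41; camera adjusted p = 0.0013, and adjusted p = 0.521 with an estimated correlation), HSP90B1 by 1.59 and HSPA5 by 1.28.

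Polysomal RNA differed less from total RNA. The largest positive differences were those of the sulfate donor synthase PAPSS2 (0.58, SE 0.10, limma adjusted p = 0.0069, n = 3 conditions), E-cadherin, CDH1 (0.56), the exosome component EXOSC3 (0.53), radixin, RDX (0.52), and G3BP2 and PPP1R12A (0.51 each). MT-RNR1 and MT-RNR2 stood at −3.68 and −3.58, the snoRNA hosts SNHG19 and SNHG5 at −2.96 and −2.86, and ferritin light chain, FTL, at −2.80. Of 1097 genes that passed, 238 were higher and 859 lower. The number was 6135 with the 24 files counted as replicates (3432 higher), 698 without the control (107 higher), 374 without the starved (4 higher) and 281 without the EGF libraries (2 higher), with nearly all higher calls lost in the last 2, and 1898 without the mP beads control library, which enters through the shared estimate of spread. Ribosomal protein mRNAs were lower in 76 of 79 cases (76 adjusted over the list alone; median −1.28; camera adjusted p = 2.04e-62, and adjusted p = 0.196 with an estimated correlation), RPLP0 by −2.28, and the other TOP mRNAs in 16 of 19 (18 adjusted over the list alone; median −0.76; camera adjusted p = 7.26e-18, and adjusted p = 0.196 with an estimated correlation), PABPC1 by −2.14. Host RNAs of snoRNAs were lower in 15 of 16 cases (16 adjusted over the list alone; median −1.43; camera adjusted p = 6.8e-21, and adjusted p = 0.196 with an estimated correlation) and mitochondrially encoded mRNAs in 12 of 13 (13 adjusted over the list alone; median −1.47; camera adjusted p = 6.1e-16, and adjusted p = 0.196 with an estimated correlation). All 28 mRNAs of secreted and membrane proteins lay above 0, 7 of them past the test (13 adjusted over the list alone; median 0.26; camera adjusted p = 1.87e-09, and adjusted p = 0.261 with an estimated correlation), CDH1 and the transferrin receptor TFRC (0.41) among them. ATF4 targets held 0 higher and 3 lower of 19 (0 and 3 adjusted over the list alone; median 0.02; camera adjusted p = 0.93). The stress transcription factors ATF4 and DDIT3, whose mRNAs carry upstream reading frames, were lower by −0.55 and −0.84.

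RiboLace was then set directly against polysomal RNA, the other measure of transcripts on ribosomes. PRPF8 (log2 difference 3.01, SE 0.23, limma adjusted p = 4.46e-05, n = 3 conditions), PRKDC (2.64), SNHG19 (2.64), FASN (2.55), TOP2A (2.48) and the laminin LAMB2 (2.43) were higher in riboLace. LINC00674 (−2.27), ZBED6 (−2.15), TBC1D14 (−1.90), TAB3-AS2 (−1.89), THRIL (−1.82) and GATC (−1.78) were lower, TAB3-AS2 being an antisense gene with uncertain reads. Of 6334 genes, 2847 were higher and 3487 lower (3123 and 3038 with median-of-ratios scaling), with 9601 when the 24 files were counted as replicates, 4111 without the starved and 2507 without the EGF libraries. Ribosome biogenesis genes were higher in 18 of 24 cases and lower in 1 (18 and 1 adjusted over the list alone; median 0.53; camera adjusted p = 1.04e-07, and adjusted p = 0.527 with an estimated correlation), RRP12 by 2.08. Ribosomal protein mRNAs were higher in 19 of 79 cases and lower in 1 (14 and 0 adjusted over the list alone; median 0.23; camera adjusted p = 0.000169, and adjusted p = 0.727 with an estimated correlation), RPS3 by 0.92. By condition their median was −0.08 in control cells, with 49 of 79 below 0, 0.54 in starved and 0.25 in EGF-treated cells. Oxidative phosphorylation mRNAs were higher in 4 and lower in 16 of 31 cases (4 and 18 adjusted over the list alone; median −0.34; camera adjusted p = 0.0174, and adjusted p = 0.727 with an estimated correlation), COX8A by −0.82.

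The mP beads libraries resembled riboLace. Within a condition the log2 levels correlated across genes at 0.973 to 0.985 between riboLace and mP beads, against 0.951 to 0.963 between riboLace and total RNA. Between riboLace and polysomal RNA it was 0.953 to 0.969. Total and polysomal RNA correlated about as highly as the pull-downs, at 0.975 to 0.979. Relative to total RNA, the same large genes led in mP beads RNA, TOP2A (log2 difference 2.32, SE 0.19, limma adjusted p = 5.21e-05, n = 3 conditions), PRKDC (2.31), PRPF8 (2.24), MYH9 (2.11) and FASN (2.02). PDCD11, at 3.28, rests on the starved library alone, where it read 885 FPKM against 17.4 FPKM in control cells, and is uncertain. MT-RNR1 (−2.34), MT-RNR2 (−2.24), MT-CO2 (−1.92), RPS29 (−1.87), LINC00674 (−1.82) and RPLP0 (−1.79) were lowest. Of 6439 genes, 2841 were higher and 3598 lower (3243 and 3144 with median-of-ratios scaling), and 2855 genes passed without the EGF libraries. Both riboLace and mP beads were higher than total RNA for 2315 genes and lower for 3176, against 636.5 and 1037.1 for independent lists. Their differences from total RNA correlated at 0.869 across genes with a covariance of 0.2331, where simulated libraries without an effect gave 0.527 and 0.0257. Part of the overlap may come from the shared total RNA libraries. The riboLace difference from total RNA in a condition was also set against the mP beads difference from total RNA in another condition. These pairs share no library, and their correlation was 0.438 to 0.66 (Spearman 0.529 to 0.782). The pairs also differ in condition, which may lower the correlation.

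Directly compared with mP beads, riboLace was lower for 9 genes and higher for 0 by limma, with 2456 genes at an unadjusted p under 0.05. With the 24 files counted as replicates the number was 4817, most of them higher (2656 higher, 2161 lower). It was 0 without the control, 3 without the starved (1 higher) and 1 without the EGF libraries (1 higher), 1 without the mP beads control library (0 higher), 0 when only the compared libraries were fitted, 1 with no filter on low values (0 higher) and 5 with a pseudocount of 0.1 (0 higher). Named by rule were MT-RNR2 (−1.01, SE 0.12, limma adjusted p = 0.0268, n = 3 conditions), MT-RNR1 (−0.94), OIP5-AS1 (−0.78), which is antisense and uncertain, and C12orf75 (−0.62). The list of mitochondrially encoded mRNAs had a median of −0.77, with none of 13 past the test over all genes and 13 lower adjusted over the list alone (camera adjusted p = 1.91e-12; adjusted p = 0.277 with an estimated correlation). Host RNAs of snoRNAs had a median of −0.49, with none of 16 past the test and 14 lower adjusted over the list alone (camera adjusted p = 8.91e-11; adjusted p = 0.277 with an estimated correlation). Of 7 nuclear-retained RNAs, none passed and 2 were lower adjusted over the list alone (median −0.21; camera adjusted p = 0.00552, and adjusted p = 0.279 with an estimated correlation). Medians for secreted and membrane proteins (0.20), cholesterol biosynthesis (0.17), ribosome biogenesis (0.14) and ER chaperones (0.14) lay above 0, with camera adjusted p-values of 5.63e-08, 2.9e-07, 0.000143 and 4.18e-05 and none of their genes past the test. With an estimated correlation these adjusted p-values were 0.357, 0.277, 0.36 and 0.36, and 1 cholesterol gene was higher adjusted over the list alone. Matched random lists also lay above 0 in each condition, at 0.04 to 0.11. The lists stood little apart from them in some conditions, as for ribosome biogenesis in control (0.11, percentile 77.72), and in starved cells ER chaperones (0.09, percentile 83.93) and cholesterol biosynthesis (0.09, percentile 87.48).

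How far a change in polysomal, riboLace or mP beads RNA departs from that in total RNA was taken as the difference of the log2 differences, with n = 1 and no test. On starvation the ribosomal protein mRNAs had a median departure of −0.64 in polysomal RNA (78 of 79 below 0, the 0th percentile of matched lists), 0.00 in riboLace (the 0.2nd percentile) and −0.09 in mP beads RNA. On EGF it was 0.73, 0.40 and 0.41, each at the 100th percentile. The other TOP mRNAs had −0.42, −0.20 and −0.16 on starvation and 0.56, 0.45 and 0.46 on EGF. Oxidative phosphorylation mRNAs departed by −0.02, 0.49 and 0.51 on starvation (matched lists −0.11, 0.19 and 0.25) and by 0.04, −0.17 and −0.14 on EGF. Host RNAs of snoRNAs departed by −0.24, −0.14 and −0.63 on starvation and by 0.32, 0.52 and 0.65 on EGF. Single genes with a departure of at least 2-fold on starvation numbered 71 in riboLace (27 higher) and 64 in polysomal RNA (26 higher), and on EGF 67 (34 higher) and 55 (30 higher). With 1 file per group they were 193 to 197 and 170 to 193 on starvation, and 166 to 190 and 162 to 165 on EGF. In polysomal RNA on starvation the first file gave more higher than lower (87 and 83) and the second fewer (78 and 115). Many of the largest are pseudogenes or overlapping genes, among them HIST1H2APS3, TMSB4XP1 and RPL39P36, so they are uncertain, and these 3 were chosen after their values were seen.

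Across genes, which are not independent replicates, the starvation changes in riboLace and total RNA correlated at Pearson r = 0.377 (Spearman 0.571), those in polysomal and total RNA at 0.434 (0.611) and those in riboLace and polysomal RNA at 0.41 (0.499). For EGF the values were 0.342 (0.517), 0.412 (0.587) and 0.32 (0.508). The fractions share no library in these 6 comparisons. With a pseudocount of 0.1 the Pearson values were 0.282, 0.319 and 0.344 on starvation and 0.239, 0.33 and 0.232 on EGF.

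**Figure D3:**
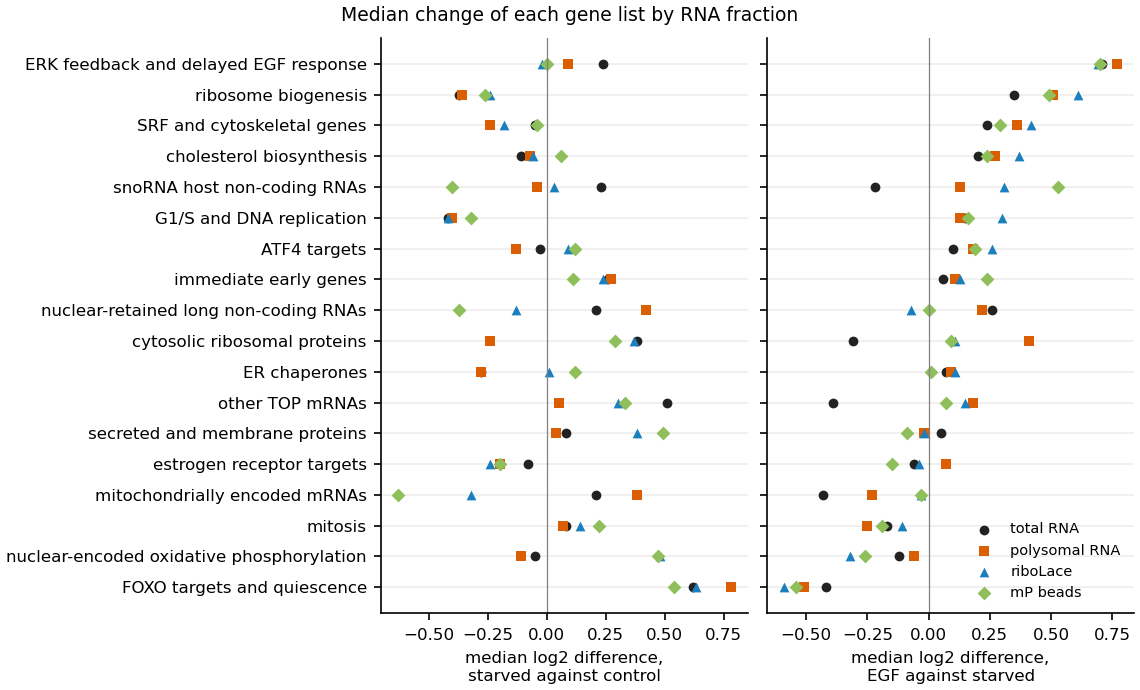
Median log2 difference (horizontal axes, on log2 of FPKM + 1) of each gene list in 4 RNA fractions, for starved against control cells (left) and EGF against starved cells (right), each n = 1 merged library per fraction and condition. FOXO targets lie between 0.54 and 0.78 on starvation and between −0.59 and −0.42 on EGF, while ribosomal protein medians spread from −0.24 to 0.38 and from −0.31 to 0.41.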

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

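All but 2 of the tests below, those on short mRNAs after starvation, were chosen only after the result was seen. Ribosomal protein mRNAs were flagged because their starvation change ran in opposite directions in different fractions: the median was 0.38 in total RNA (78 of 79 above 0) and −0.24 in polysomal RNA (74 of 79 below 0), a median difference of −0.64, which was not tested. The change in riboLace differed from that in polysomal RNA by 0.64 and that in mP beads RNA by 0.55, both flagged for opposite directions and not tested. Matched random lists went in the same opposite directions, with medians of −0.11 in polysomal RNA, 0.31 in riboLace and 0.32 in mP beads RNA. They could include ribosomal protein genes themselves, so how far other abundant genes share these gaps cannot be told. On EGF the polysomal and total RNA changes of the same list differed by 0.73, in the other direction, and this was not tested. Mitochondrially encoded mRNAs were flagged because on starvation 12 of 13 lay above 0 in total RNA and 12 of 13 below 0 in riboLace (difference −0.58) or all 13 below 0 in mP beads RNA (difference −0.86), and neither was tested.

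For the ribosomal protein mRNAs, a scale factor, which moves all genes alike, was excluded as the whole cause, since the difference lay −0.44 from that of matched random lists (−0.20). Loss of short mRNAs from the starved polysomal library may account for part: 50 other protein-coding genes with a locus under 2000 bases had a median of −0.26 (95% interval −0.34 to −0.18), against −0.05 in matched lists, while no gain of short mRNAs was seen on EGF (0.02, interval −0.02 to 0.07). These intervals come from resampling the genes and hold no spread between libraries or cultures. Lower polysome loading of TOP mRNAs in starved cells fits, since the other TOP mRNAs differed by −0.42 on starvation, at percentile 0.3 of matched lists, and by 0.56 on EGF. The EGF value is not particular to polysomes, since these mRNAs departed from total RNA nearly as far in riboLace and mP beads RNA. Other short genes also lay below their matched lists on starvation, so the starvation value does not single out lower loading. In riboLace the ribosomal protein mRNAs departed from total RNA by 0.00 on starvation, though below matched lists, and the other TOP mRNAs by −0.20. An unusual preparation of the starved samples cannot be told apart from lower loading. Both directions rest on the same starved libraries, and EGF against control gave only 0.11. New cultures of starved cells would separate them.

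The riboLace and mP beads libraries of each condition were alike, with correlations of 0.973 to 0.985, as were total and polysomal RNA (0.975 to 0.979). One library under 2 labels was excluded for riboLace and mP beads. Their files differed by a chi-square of at least 1160 over 9 mitochondrial genes, beyond the 3.15 to 36.4 of files of a group. Over genes with 5 to 29 reads the starved pair did not stand apart. Its median chi-square was 1.069 times that expected, against 1.082 to 1.151 times within groups. RNA held by the beads themselves in both pull-downs remains possible. Mitochondrially encoded mRNAs, which cytosolic ribosomes do not translate, had a median of −0.77 in riboLace against mP beads. None passed the test over all genes, and the list did not pass camera with an estimated correlation. The amounts of RNA recovered are not given, so the share of background cannot be told.

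Oxidative phosphorylation mRNAs had starvation changes 0.49 higher in riboLace than in total RNA, against 0.19 in matched random lists. The polysomal difference from total RNA was −0.02 (quartiles −0.13 to 0.07), against −0.11 in matched lists, and since the loss of short mRNAs from the same library may hide a rise, entry into polysomes cannot be told apart. A gain of short mRNAs in the pull-downs cannot be told apart, since other short genes had 0.24 (95% interval over genes 0.19 to 0.32), against 0.08 in matched lists.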

How the results depend on the processing

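Named genes that passed kept their direction throughout: of 7962 values of a gene in a setting, 7552 stayed on the same side of the threshold, 410 lost the call and 0 reversed. Named genes that did not pass were not counted. The largest rises and falls had been chosen for the same direction in all compared libraries, so few reversals could occur. The condition counts stayed within 1.5 times under every alternative that merged the files, with leave-one-out ranges over fractions of 4065 to 5639 (starved against control), 2405 to 3604 (EGF against starved) and 4764 to 5005 (EGF against control). For starved against control, 4219 and 4065 genes passed without riboLace or mP beads, against 5639 and 5594 without total or polysomal RNA. For EGF against starved these were 2405 and 2528, against 3565 and 3604. The 2 pull-downs, alike in level, count as separate fractions in these fits. Part of the calls may therefore rest on their agreement with each other, which was not tested. Estimated depths of 11.2 to 17.1 M reads limit genes near 1 FPKM most. The cause was not tested for any value below unless its construction shows it. With the 24 files as replicates, which takes the 2 files of a group as independent, counts were 8831 (starved against control), 7949 (EGF against starved), 8982 (EGF against control), 6135 (polysomal against total RNA), 9601 (riboLace against polysomal RNA) and 4817 (riboLace against mP beads).

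With the replicate number as a block in that fit of 24 files, the condition counts were 8709, 7822 and 8877. Fractions were instead fitted additively, as fraction plus condition with replicate number. That fit also moves differences between conditions into the spread. It gave 3628 for polysomal against total RNA and 1904 for riboLace against mP beads, which cannot be credited to the block alone. No other count moved by over 1.5 times. Same-numbered deviations correlated at −0.124 to 0.126 over 66 pairs of groups. Since the files of a group were so alike, this cannot tell whether the numbers pair the samples. RiboLace counts against mP beads, 9 in the main fit, were 5 with a pseudocount of 0.1, 1 with no filter on low values, 0 with only the compared libraries and 1 without the mP beads control library, which gave 1898 for polysomal against total RNA. Leaving out 1 condition, fewer libraries, gave 4831 to 6648 for riboLace against total RNA, 281 to 698 for polysomal against total RNA, 2507 to 5933 for riboLace against polysomal RNA, 0 to 3 for riboLace against mP beads and 2855 to 5784 for mP beads against total RNA. Without a replicate, polysomal against total RNA gave 749 to 864 and riboLace against mP beads 1 to 5.

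The count of genes 2-fold apart in mP beads RNA on starvation was 410 among genes with a mean of at least 5 FPKM. Single files, which drop the requirement that files do not overlap, gave for starved against control 331 to 332 (total RNA) and 336 to 360 (polysomal RNA), and for EGF against starved 203 to 215, 203 to 214, 204 to 241 (riboLace) and 246 to 252 (mP beads). They gave 411 to 422 for EGF against control in total RNA, and for departures from total RNA 193 to 197 (riboLace) and 170 to 193 (polysomal RNA) on starvation, and 166 to 190 and 162 to 165 on EGF.

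Correlations are given in the order riboLace with total, polysomal with total and riboLace with polysomal RNA. A pseudocount of 0.1 gave 0.282, 0.319 and 0.344 on starvation and 0.239, 0.33 and 0.232 on EGF. With small RNA genes kept they were 0.236, 0.272 and 0.233, and 0.228, 0.241 and 0.141. With no filter the EGF value of polysomal with total RNA was 0.354. Single files gave 0.304 to 0.322, 0.35 to 0.372 and 0.346 to 0.362 on starvation, and 0.247 to 0.262, 0.289 to 0.318 and 0.237 to 0.31 on EGF. Of 152 gene list tests, 80 passed at the preset correlation and 4 with an estimated correlation.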

Other observations

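The groupings below were counted, and the lists here picked out, only after the results were seen. Of the list results between fractions, only some are given above and here, and none passes with an estimated correlation. Cholesterol biosynthesis mRNAs were higher in riboLace than in total RNA in 13 of 23 cases and lower in 3 (14 and 3 adjusted over the list alone; median 0.27; camera adjusted p = 0.00261, and adjusted p = 0.521 with an estimated correlation), and so were SRF and cytoskeletal genes, 11 higher and 2 lower of 17 (11 and 3 adjusted over the list alone; median 0.59; camera adjusted p = 0.00197, and adjusted p = 0.488 with an estimated correlation). Host RNAs of snoRNAs were higher in riboLace than in polysomal RNA in 11 of 16 cases and lower in 1 (12 and 1 adjusted over the list alone; median 1.02; camera adjusted p = 2.83e-05, and adjusted p = 0.527 with an estimated correlation), SNHG3 by 1.53. On starvation the hosts held 2 higher and 5 lower of 16 (3 and 5 adjusted over the list alone), with a median of 0.00, and did not pass (camera adjusted p = 0.544). Among the lower, SNHG3, SNHG12, SNHG15 and SNHG17 fell by 0.95, 0.86, 0.74 and 0.68.

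All groupings of the merged libraries into sets of equal size were counted with limma, on values centred by the other factor. For starved against control the real grouping gave 6443 genes and the highest of the others 2, for EGF against starved 5582 and 0, and for EGF against control 6670 and 1, so that 1 of 35 groupings reached the real count in each. For fractions, 1 of 10 groupings reached the real count for riboLace against total RNA (8303, highest other 1), polysomal against total RNA (1605 and 0), riboLace against polysomal RNA (7244 and 1) and mP beads against total RNA (7394 and 1). Every other grouping mixes libraries of both sides, so a real difference adds to its spread and lowers its count. The low counts of the other groupings therefore do not show how many genes chance gives. The groupings also did not keep the libraries of a fraction, or of a condition, paired. Chance is thus not excluded by these counts, for conditions or for fractions. With the 10 groupings of the fractions the share also cannot fall under 0.05. For riboLace against mP beads the real grouping gave 0 and the highest other 2, so that 10 of 10 reached it.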
